A study of Mus musculus with 4 samples.

How the data were processed

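The series holds 4 samples of mouse splenic regulatory T cells. Per the labels' protocols, CD4 cells were enriched magnetically from the spleens of mice aged 7 to 8 weeks and sorted for green fluorescence driven by Foxp3, which gave 15000 to 40000 cells per sample. RNA was isolated with a column kit. The extract and label fields then describe real-time PCR with SYBR dye, although the series is typed as expression profiling by array, so the labelling and hybridisation steps are not given in the sources used here. The groups were taken from the sample titles: WT replicates 1 and 3 and KO replicates 1 and 2. The labels give no batch, scan date or slide, so none could be tested.

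The authors deposited 1 table of log2 expression values, with 65528 transcript clusters and 4 arrays. Per the submitters' processing notes, the tools were RMA (robust multi-array averaging) and Transcriptome Analysis Console, without a version or order. The log base is taken as 2 because RMA reports log2 and because the values run from 1.82 to 19.38. The columns are neither centred nor forced to 1 common distribution at this level, since their medians differ slightly (4.65 to 4.72). The array's background handling, genome build and annotation version are not given in the sources used here. All 4 columns of per-sample values were used, and 0 were left out.

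Clusters were named through the platform annotation table supplied with the values. Of the 65528 clusters, 30871 had 1 gene symbol, 1646 had several and 33011 were not listed there. Symbols were updated through gene identifiers and synonyms of the RefSeq annotation of mouse assembly GRCm38.p6, which was used only for names, gene types and which genes neighbour each other. It named 22634 clusters through the identifier and changed 1131 symbols. No gene was named from a cluster with several symbols. For the 418 genes with more than 1 cluster, the one with the highest mean over the 4 arrays was kept, which left 30351 genes. No filter on dim genes was applied in the reported test, since the table carries no detection call.

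Differences were tested on the log2 scale as KO minus WT with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The estimated prior degrees of freedom were 3.16, and the median standard error of a difference was 0.12. Fold values are powers of 2 of these differences, and intervals are 95% intervals from the same fit. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333, so no exact test could pass the threshold, and the p-values reported come from limma. Gene lists were compared with the other genes by limma's camera test with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. There were 42 lists, and the 41 with at least 4 measured members were tested. They held 671 measured entries. The list of replication-dependent histones had 3 measured members and was not tested: H1f5 differed by 0.09 (SE 0.07), H1f2 by 0.77 (SE 0.48) and H3c3 by -0.14 (SE 0.11).

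The test, the gene lists, the alternatives and the rule for the genes named in the text were fixed before the data were examined. The rule takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays do not overlap between groups. Where a direction had fewer, it was filled with the genes of smallest p with the same separation, given as not past the threshold. Predicted genes and receptor segments were passed over, 11 among the higher and 8 among the lower genes. Also named in every case were Bmi1, Foxp3, Il2ra, Ctla4, Ikzf2, Cdkn2a, Tbx21, Ifng, Il17a, Gata3 and Il10, and up to 4 members of each list described. A further gene of the rule is not reported here.

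The procedure was tested on simulated data for the comparison of KO against WT, with 200 changed genes among 30351. It called 49.3% of the genes changed by a log2 value of 1, 97.0% of those changed by 2 and 100% of those changed by 3, with 5 unchanged genes called and 0 wrong signs. Of the unchanged genes, 5.09% had an unadjusted p under 0.05. An adjusted p depends on how many genes change, so these shares hold for 200 changed genes and not for the measured data. There, Nrn1 differed by 2.94 (limma adjusted p 0.141) and Mir3094 by -2.36 (limma adjusted p 0.121), and neither passed. In the simulated list test, a list shifted by 0.5 gave limma camera p of 1.53e-25 with the preset and 0.0189 with an estimated correlation. Of 100 unshifted lists, 5 and 0 had a p under 0.05. The simulated genes were drawn independently, so these counts do not show how the list test behaves for genes that vary together.

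The alternatives were median-centred values, a further quantile normalization, a filter on dim genes, the mean of all clusters of a gene, eBayes without a trend or with robust settings, leaving out each array in turn, other thresholds, all clusters whether named or not, and, for the lists, an estimated correlation and 10000 random lists matched on mean expression. A fit to protein-coding genes alone was added after seeing the data. Tables were joined in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.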

Results

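Gene expression was measured on 1-colour arrays in regulatory T cells from mouse spleen, the CD4 T cells that express the transcription factor Foxp3 and restrain immune responses. The cells were sorted by a green fluorescent protein that is made together with Cre recombinase under Foxp3 control. Control mice carried this Cre transgene alone (labelled WT). In the other group it was combined with a floxed Bmi1 allele, so that Bmi1, a subunit of Polycomb repressive complex 1, would be deleted in Foxp3-expressing cells (labelled KO). The design compares the 2 genotypes with 2 arrays each: WT replicates 1 and 3, and KO replicates 1 and 2. The titles and the treatment field describe resting cells, whereas the series text describes 24 h of stimulation through CD3 and CD28, and the labels do not settle which holds. The array medians were 4.72 and 4.67 (WT replicates 1 and 3) and 4.65 and 4.69 (KO replicates 1 and 2) on the log2 scale. Across transcript clusters, which are not independent replicates, Pearson's r was 0.993 for the WT pair, 0.994 for the KO pair and 0.991 to 0.992 between groups. Nothing in the labels says whether the samples came from separate animals, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

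The targeted gene was examined first. Bmi1 had a mean of 8.98 ± 0.00 (SD, n = 2) in the arrays labelled WT and 9.75 ± 0.23 (SD, n = 2) in the arrays labelled KO. The difference was 0.77 on the log2 scale (SE 0.16), a 1.70-fold higher level with a 95% interval of 1.28 to 2.25 and a limma adjusted p of 0.300. Both arrays labelled KO (9.58 and 9.91) lay above both arrays labelled WT (8.98 and 8.98), the opposite of what the genotype label states. Bmi1 had 1 value per array, for transcript cluster TC0200000302.mm.1. The sources do not say which exons that cluster covers or which were floxed, and a cluster outside the deleted part checks nothing. Every direction given here therefore rests on the labels alone, and the groups are called the arrays labelled KO and the arrays labelled WT throughout.

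Snord14e and Igf2bp3 rose in the arrays labelled KO, and no gene fell, at a Benjamini-Hochberg adjusted p under 0.05 (limma, 30351 genes). Snord14e, a small nucleolar RNA of the class that guides ribosomal RNA modification, went from 12.70 ± 0.37 to 16.98 ± 0.08 (SD, n = 2 each). Its difference was 4.28 on the log2 scale (SE 0.18), 19.43-fold, with a limma adjusted p of 0.0470. The value is that of cluster TSUnmapped00000178.mm.1, whose identifier gives no chromosome, and where that cluster maps was not examined. Igf2bp3, an RNA-binding protein best known from fetal tissues, went from 4.63 ± 0.14 to 7.11 ± 0.01 (SD, n = 2 each), a difference of 2.48 (SE 0.12), 5.56-fold, with the same limma adjusted p of 0.0470. The arrays labelled WT put Igf2bp3 below the median gene of each array. The table has no background measure, so the difference of any gene that reads below the median gene in a group can understate its change, which holds for Igf2bp3 and, among the genes named next, for Mir32 (3.38 and 3.35 in the arrays labelled WT) and for Lalba (4.30 and 4.32) and Mir505 (4.93 and 4.50) in the arrays labelled KO. Both calls ended without any 1 of the 4 arrays, where limma adjusted p lay between 0.546 and 0.802 for both genes, although their differences stayed within 4.02 to 4.54 for Snord14e and 2.38 to 2.58 for Igf2bp3. On all 4 arrays both also ended after a further quantile normalization (limma adjusted p 0.113 for both), without an intensity trend (0.0890) and with robust settings (0.0621 and 0.0650), and Igf2bp3 ended after median-centring (0.0606) and over all clusters (0.113).

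The other genes with the smallest p among those higher in both arrays labelled KO did not pass. Ighg2b, an immunoglobulin heavy chain constant gene, differed by 1.81 (SE 0.12, 3.51-fold, limma adjusted p 0.106). Nlrp1a, an inflammasome sensor, differed by 1.67 (SE 0.15, 3.17-fold), and Casp1, the protease that inflammasomes activate, by 1.43 (SE 0.13, 2.69-fold), both with a limma adjusted p of 0.121. Scg5, a chaperone of a prohormone convertase, differed by 1.73 (SE 0.16) and Ntn4, a secreted netrin, by 1.58 (SE 0.15). Tmem181a differed by 1.57 (SE 0.12), Zfp414 by 1.48 (SE 0.13) and the microRNA gene Mir32 by 1.19 (SE 0.11). Limma adjusted p for these last 5 lay between 0.121 and 0.122.

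No gene passed in the other direction, and those with the smallest p are given as values. Kbtbd11 had a difference of -1.13 (SE 0.08), 0.457 times the level of the arrays labelled WT, with a limma adjusted p of 0.106. Gpr15, a receptor that directs T cells to the large intestine, had a difference of -1.41 (SE 0.13), 0.376 times, with a limma adjusted p of 0.121. Ppp1r3e, a glycogen-targeting subunit of a protein phosphatase, had -1.65 (SE 0.16), Rcn2, a calcium-binding protein of the endoplasmic reticulum, -1.18 (SE 0.15), and Aqp3, a water and glycerol channel, -0.95 (SE 0.10). Lalba, known as a milk protein gene, had -1.14 (SE 0.12). Among small RNAs, Mir3094 had -2.36 (SE 0.19), Mir505 -1.47 (SE 0.17), the ribosomal RNA pseudogene n-R5s41 -1.25 (SE 0.12) and Rn4.5s -0.73 (SE 0.09). Limma adjusted p for these last 8 lay between 0.121 and 0.206.

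**Figure D1:**
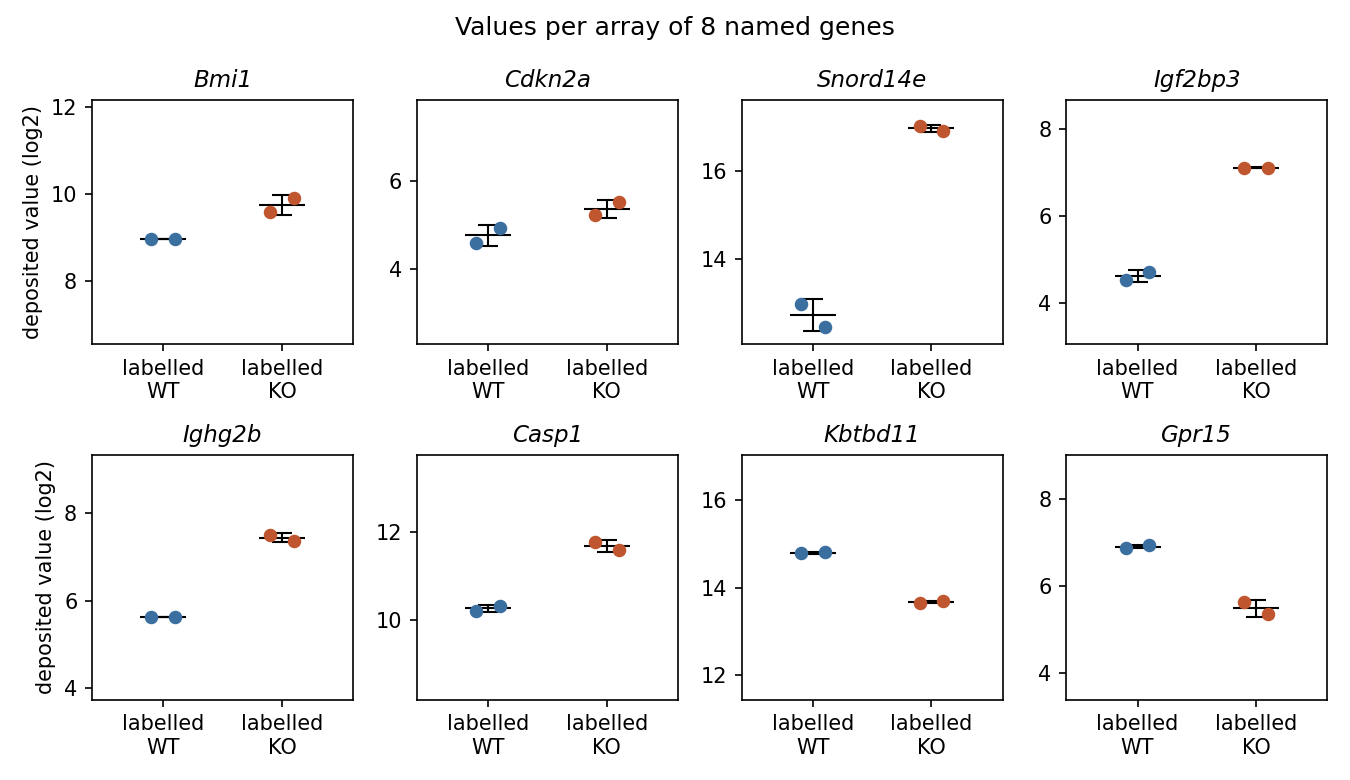
Deposited log2 values of 8 named genes, with 1 point per array, grouped by label on the horizontal axis; dashes are group means and bars are SD (n = 2), and every vertical axis spans the same range around the gene's midpoint. Bmi1 lies at 8.98 in both arrays labelled WT and at 9.58 and 9.91 in the arrays labelled KO, and Snord14e and Igf2bp3 are the 2 genes past the threshold.

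In all, 3056 of the 30351 genes had an unadjusted limma p under 0.05, 1918 of them higher and 1138 lower in the arrays labelled KO, where 1518 would be expected by chance. The balance was more even among the 18958 protein-coding genes, of which 1313 had such a p, 688 higher and 625 lower. Most of the excess over chance, and of the upward balance, therefore lay among the entries that are not protein-coding. At least a 2-fold difference was seen for 205 genes, 118 higher and 87 lower. The arrays of the groups did not overlap for 6347 genes with the arrays labelled KO higher and 5319 with them lower, together 38.4% of genes against 33.3% by chance. When only the 15176 genes in the brighter part of the range were tested (mean at or above 5.03), 14 passed a limma adjusted p under 0.05, 10 higher and 4 lower, with Snord14e and Igf2bp3 among them. The others that rose in that test were Ighg2b, Tmem181a, the predicted gene Gm15428 and immunoglobulin heavy chain variable segments, among them Ighv1-2 (3.18, SE 0.25), Ighv1-55 and Ighv1-64. Those that fell were Kbtbd11, Mir3094 and the T cell receptor alpha segments Trav4d-4 (-2.63, SE 0.21) and Traj3 (-3.14, SE 0.20).

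The regulatory T cell, helper T cell and cell cycle genes named in advance did not pass. Il2ra, the interleukin-2 receptor chain CD25, differed by 0.02 (SE 0.07), the inhibitory receptor gene Ctla4 by 0.05 (SE 0.17) and the transcription factor gene Ikzf2 by -0.16 (SE 0.12). The 95% intervals were -0.16 to 0.19 for Il2ra, -0.38 to 0.47 for Ctla4 and -0.46 to 0.15 for Ikzf2. Tbx21, the Th1 regulator, differed by 0.10 (SE 0.15), Ifng by -0.02 (SE 0.23), Il17a by -0.15 (SE 0.08) and Il10 by 0.28 (SE 0.32). Cdkn2a, the cell cycle inhibitor locus that Bmi1 is known to repress, differed by 0.61 (SE 0.16), 1.52-fold higher in the arrays labelled KO, with a limma adjusted p of 0.377. It lay below the median gene in both arrays labelled WT (4.60 and 4.94). Foxp3 and Gata3 each lay on a cluster shared with other genes, and no value is given for them.

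Of 41 gene lists with enough measured members, 5 passed an adjusted p under 0.05 in limma's camera test with a preset correlation of 0.01, 3 of them up and 2 down in the arrays labelled KO. None of the 5 held with an estimated correlation. That setting has little power on 4 arrays. In the simulation it gave a list shifted by 0.5 a limma camera p of 0.0189, against 1.53e-25 with the preset. The estimate was below the preset for the Th2 (-0.12) and the cell cycle G2 and M lists (-0.02). It was above for ribosomal (0.07), plasma cell (0.17) and interferon genes (0.43). For the Th2 and the cell cycle lists, a higher correlation among the members therefore cannot account for the lost call. For ribosomal, plasma cell and above all interferon genes it may have contributed. The simulated genes were independent, so low power and correlation cannot be told apart for these lists. Over all genes tested, 0 members of any list passed.

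The ribosomal protein list, structural components of the ribosome, passed upward in the camera test. All 19 measured members were higher in the arrays labelled KO, by a mean of 0.13 on the log2 scale, with a camera adjusted p of 7.65e-04 in limma and an adjusted p = 0.943 with an estimated correlation. The examples are Rps15 (0.17, SE 0.05), Rpl27 (0.13, SE 0.04), Rps7 (0.14, SE 0.05) and Rpl19 (0.14, SE 0.06). Adjusted over the list alone, 0 members passed in either direction, as over all genes. The list median of 0.13 lay at the 54.4th percentile of 10000 random lists matched on mean expression, so these genes were not higher than other genes of similar level. After a further quantile normalization the mean was 0.08, the limma camera adjusted p was 0.502 and Rps7 had -0.02.

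The plasma cell list, genes of antibody-secreting cells, also shifted up, with 8 of 9 members higher and a mean of 0.46 (limma camera adjusted p 0.00104, adjusted p = 0.943 with an estimated correlation). Adjusted over the list alone, 3 members rose and 0 fell, against 0 over all genes. These were Ighg2b (1.81, SE 0.12), Jchain, which joins antibody units (1.03, SE 0.13), and Mzb1, an antibody folding factor (0.40, SE 0.10), while Derl3 had 0.27 (SE 0.12). Immunoglobulin segments moved in the same direction: 90 of 112 heavy chain and 64 of 86 kappa chain variable segments were higher in the arrays labelled KO, with medians of 0.44 and 0.16. The B cell marker list gave no such shift, with 5 of 13 members higher, 6 lower and a limma camera adjusted p of 0.911. Without WT replicate 1 the plasma cell call was lost, with a mean of 0.41 and a limma camera adjusted p of 0.137, and among the brighter genes alone the mean was 0.78 (0.0173).

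The interferon response list, antiviral genes induced by interferons, shifted down, with 23 of 31 members lower, 8 higher and a mean of -0.26 (limma camera adjusted p 0.00391, adjusted p = 0.988 with an estimated correlation). Adjusted over the list alone, 2 members rose and 5 fell, against 0 over all genes. The examples are Usp18, a negative regulator of interferon signalling (-1.44, SE 0.20), the oligoadenylate synthetase Oas3 (-0.91, SE 0.16), the viral tether Bst2 (-0.48, SE 0.10) and, upward, the GTPase Igtp (0.47, SE 0.10). The list mean was 9.13 in WT replicate 1, 8.86 in WT replicate 3, 8.81 in KO replicate 1 and 8.65 in KO replicate 2. Without WT replicate 1 the mean difference was -0.12 (limma camera adjusted p 0.295), and without KO replicate 2 it was -0.18 (limma camera adjusted p 0.207). Without WT replicate 3 it was -0.39 (limma camera adjusted p 2.82e-04).

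The Th2 list shifted down, with 8 of 9 members lower and a mean of -0.24 (limma camera adjusted p 0.0242, adjusted p = 0.943 with an estimated correlation). Its leading members are the receptor genes Ccr4 (-0.76, SE 0.18), Ccr3 (-0.26, SE 0.08), Il4ra (-0.65, SE 0.22) and Ptgdr2 (-0.16, SE 0.11). In mean level, 6 of the 9 members lay below the median gene, Ccr3, Ptgdr2 and the cytokine genes of the list among them. Adjusted over the list alone 0 members passed, as over all genes. The call was lost without WT replicate 1 (mean -0.25, limma camera adjusted p 0.137), without WT replicate 3 (-0.23, 0.178) and without KO replicate 2 (-0.21, 0.10), although the mean moved little.

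The list of genes active in the G2 and M phases of the cell cycle shifted up, with 20 of 26 members higher and a mean of 0.18 (limma camera adjusted p 0.0277, adjusted p = 0.943 with an estimated correlation). The examples are the proliferation marker Mki67 (1.17, SE 0.32), cyclin gene Ccna2 (0.62, SE 0.16), the spindle factor Tpx2 (0.65, SE 0.18) and Birc5 (0.23, SE 0.07). In mean level, 10 of the 26 members lay below the median gene, among them Birc5 (3.27 to 3.54 in the 4 arrays). Tpx2 read 4.80 and 4.83 in the arrays labelled WT. Adjusted over the list alone 0 members passed, as over all genes. The call was lost without WT replicate 1 (mean 0.13, limma camera adjusted p 0.137), without KO replicate 1 (0.15, 0.202) and among the brighter genes alone (0.25, 0.267), with the mean above 0 in each. The G1 and S phase list did not pass, with 14 of 22 members higher (limma camera adjusted p 0.747).

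**Figure D2:**
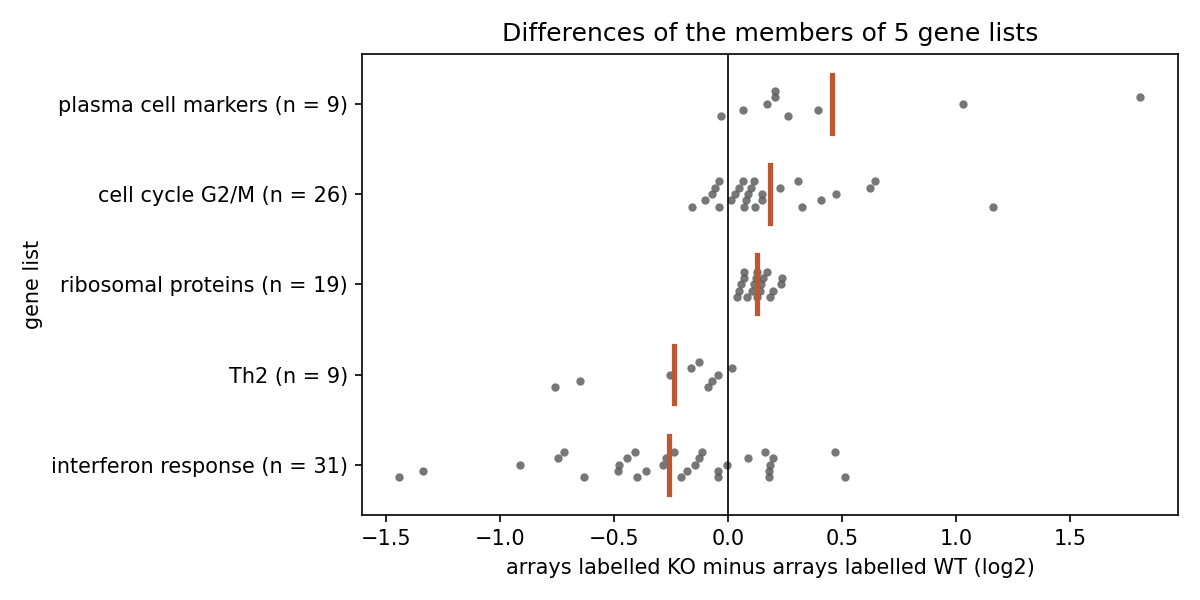
Differences of the measured members of the 5 gene lists past the threshold, with 1 point per gene; the horizontal axis is the log2 difference between the arrays labelled KO and labelled WT, points are spread vertically for visibility, and the thick line is the list mean. All 19 ribosomal protein genes lie above 0 (Rps7 lies at -0.02 after a further quantile normalization), whereas 23 of 31 interferon response genes lie below it. The median of the ribosomal list lay at the 54.4th percentile of random lists matched on mean expression.

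Polycomb-related lists did not pass in the camera test. In the list of Polycomb repressive complex 1 subunits 12 of 18 members were higher (limma camera adjusted p 0.313), and adjusted over the list alone 2 rose and 0 fell, against 0 over all genes: Bmi1 itself and the chromodomain subunit gene Cbx8 (0.70, SE 0.15). Ring1, a ubiquitin ligase subunit, had 0.34 (SE 0.11). In complex 2, which methylates histone H3, 7 of 12 members were higher (limma camera adjusted p 0.747). Hox genes, classical Polycomb targets, were higher for 24 of 33 members (limma camera adjusted p 0.313), with Hoxa6 at 0.43 (SE 0.12) and Hoxa5 at 0.28 (SE 0.10). Its median lay at the 99.9th percentile of random lists matched on mean expression. The Hox list passed that test (Benjamini-Hochberg adjusted p 0.0349 over the 41 lists, from the percentile among random lists). The test draws random genes and treats members as independent, so it does not measure the spread between arrays. With an estimated correlation the limma camera adjusted p was 0.988. The mean level of the Hox list lay between 3.80 and 3.90 in the 4 arrays, and 32 of its 33 members lay below the median gene. Other developmental targets were higher for 33 of 57 members (limma camera adjusted p 0.835). In the list of cyclin-dependent kinase inhibitors and senescence genes 9 of 11 members were higher (limma camera adjusted p 0.0998), and adjusted over the list alone 1 rose, Cdkn1a (1.02, SE 0.11), against 0 over all genes. Cdkn1a was also the 1 member of 16 that rose in the list of p53 targets adjusted over the list alone, of which 8 were higher and 8 lower (limma camera adjusted p 0.879).

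Lists of T cell identity and function did not pass either. In the regulatory T cell core list 11 of 20 members were higher and 9 lower (limma camera adjusted p 0.911), among them Lrrc32, the anchor of latent TGF-beta (-1.34, SE 0.25), Gpr83 (1.15, SE 0.28) and the ectonucleotidase gene Entpd1 (-0.69, SE 0.26). Adjusted over the list alone 0 of these passed, while Lrrc32 fell adjusted over the TGF-beta signalling list alone, where 7 of 16 members were higher (limma camera adjusted p 0.747). In the effector regulatory T cell list 9 of 17 were higher (limma camera adjusted p 0.972), with Klrg1 at -0.59 (SE 0.14). Of naive and central T cell genes 4 of 14 were higher (limma camera adjusted p 0.747), and adjusted over the list alone the lymph node homing receptor gene Ccr7 rose (0.62, SE 0.11) and the interleukin-7 receptor gene Il7r fell (-0.93, SE 0.15). In the list of gut and tissue homing genes 11 of 17 were higher (limma camera adjusted p 0.860), and adjusted over the list alone Ccr7 and Cd44 (0.51, SE 0.13) rose and Gpr15 and Ccr4 fell, 2 each way against 0 over all genes. Conventional CD4 effector markers were higher for 9 of 12 members (limma camera adjusted p 0.131), and adjusted over the list alone the T cell receptor complex gene Cd3e rose (0.57, SE 0.06).

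Among the remaining T cell programmes, 8 of 15 Th1, 9 of 15 Th17 and 7 of 11 follicular helper genes were higher, with limma camera adjusted p of 0.987, 0.864 and 0.864. Leading members were Tnf (-0.68, SE 0.20) and Btla (-0.54, SE 0.11). Of genes in IL-2 and STAT5 signalling 4 of 13 were higher (limma camera adjusted p 0.548), of NF-kB and TNF signalling 8 of 18 (0.856) and of apoptosis regulators 7 of 16 (0.856). Stress genes of the immediate early and sorting response were higher for 13 of 22 members (limma camera adjusted p 0.313), and adjusted over the list alone 3 rose and 0 fell: the chaperone genes Hspa1a (1.92, SE 0.25) and Dnajb1 (0.59, SE 0.12) and the phosphatase gene Dusp1 (0.44, SE 0.09). Oxidative phosphorylation genes were higher for 24 of 30 members (limma camera adjusted p 0.313), with cytochrome c gene Cycs at 0.43 (SE 0.08). Their median of 0.065 lay only at the 9.8th percentile of random lists matched on mean expression, so they were not higher than other genes of similar level. Glycolysis was higher for 10 of 14 (limma camera adjusted p 0.579), cholesterol synthesis for 10 of 15 (0.747) and the unfolded protein response for 7 of 16 (0.972).

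Markers of other cells that the sort could hold did not pass apart from those of plasma cells, whose call was lost at an adjusted p = 0.943 with an estimated correlation (limma camera). CD8 T cell and NK markers were higher for 9 of 14 members (limma camera adjusted p 0.569), led by Nkg7 (1.16, SE 0.32) and Eomes (1.08, SE 0.37). Macrophage and monocyte markers were higher for 8 of 19 and lower for 11 (limma camera adjusted p 0.747), neutrophil markers higher for 8 of 14 (0.911) and dendritic cell markers for 4 of 13 (0.747). In the dendritic cell list Bst2 fell adjusted over the list alone. Antigen presentation genes of MHC class II were higher for 6 of 8 (limma camera adjusted p 0.747), and adjusted over the list alone H2-Ob fell (-0.79, SE 0.14). Erythroid markers were higher for 5 of 8 (limma camera adjusted p 0.640), platelet and megakaryocyte markers for 1 of 8 (0.579), mast cell and basophil markers for 5 of 8 (0.864), stromal and endothelial markers for 6 of 13 (0.747) and gamma delta and NKT markers for 2 of 5 (0.972). Sex markers gave the same pattern in all 4 arrays, with Xist between 4.75 and 4.84, the Y-linked gene Eif2s3y between 9.69 and 9.99, and a limma camera adjusted p of 0.569 for the 4 measured members. In level, 2 of these members were higher and 2 lower in the arrays labelled KO. Both lower ones did not overlap between groups, with a lowest difference of -0.42, and 1 had an unadjusted limma p under 0.05. In 9 of the 36 lists that did not pass, the median, the mean and the direction of the test differed in sign, among them the regulatory T cell core, Th1 and macrophage lists.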

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

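The fit to protein-coding genes was chosen after seeing the data. The 2 genes past the threshold became 1 after median-centring (Snord14e kept, 3136 genes at an unadjusted p under 0.05) and 0 after a further quantile normalization (3005), without an intensity trend (3094) and with robust settings (2992). Leaving out each array in turn gave 0 to 0 genes by limma (1674 to 2777 at an unadjusted p under 0.05); the lone array of a group is then assumed to vary like the other group. Testing the brighter genes alone gave 14 genes, a fit to all clusters 4 (1 up, 3 down), protein-coding genes alone 1 (Igf2bp3), and an unadjusted p under 0.05 with at least a 2-fold change 166. Fewer tests or fewer arrays are part of the filter and leave-out settings; for the others the cause was not tested. The count stayed at 2 with the mean of clusters, a 2-fold minimum and an adjusted p under 0.10.

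The 5 lists became 0 with an estimated correlation, a setting with little power on 4 arrays. The percentile among random lists gave 2 (Hox genes up, interferon response down, 1 shared). Leaving out arrays gave 1 to 5 lists, with 1 without WT replicate 1 (ribosomal proteins) and 3 without KO replicate 2; the cause was not tested. Other settings gave 4 or 5. The robust setting does not enter the list test. Bmi1 stayed higher in the arrays labelled KO in all 10 settings, by 0.60 to 0.93, with limma adjusted p from 0.181 to 0.802.

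Of 177 genes named or leading their lists, 12 changed sign somewhere, 17 values in all, none called in either setting; the cause was not tested. Median-centring gave Ifng 0.01. Quantile normalization gave Il2ra -0.105, Ctla4 -0.045, Ifng 0.0175, Cox5b -0.02 and Rps7 -0.0244. Leaving out each array in turn gave Ifng -0.28 to 0.25, Ctla4 -0.16 to 0.25, Il10 -0.21 to 0.76, Tbx21 -0.05 to 0.25, Xist -0.04 to 0.05, Gp5 -0.31 to 0.02, Klrb1c -0.34 to 0.09, Zbtb16 -0.05 to 0.12 and Fcer2a -0.03 to 0.20.

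No paired analysis was possible because the groups share only replicate number 1. The 4 arrays make 3 splits into pairs, too few for a share under 0.05: the real one gave 2 genes and the highest other 0. The value table carries no background measure, so signal over background was not used here.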

Other observations

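The genes in the first 3 paragraphs, the test of swapped labels and both tests of genome position were chosen after the values were seen; the test of the genes around Bmi1 and both tests of immunoglobulin segments were written before.

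Some genes of the inflammasome and of interleukin-1 control had higher values in the arrays labelled KO and others did not; no member passed over all genes by limma, and they were not tested as a group. Beside Casp1 (1.43) and Nlrp1a (1.67), the adaptor gene Pycard differed by 1.04 (SE 0.18), the related caspase gene Casp4 by 0.96 (SE 0.14), the decoy receptor gene Il1r2 by 1.93 (SE 0.28) and the antagonist gene Il1rn by 1.21 (SE 0.20). Among other such genes, Nlrp3 differed by 0.01 (SE 0.11), Aim2 by 0 (SE 0.13), Il1b by -0.02 (SE 0.11), Il18 by -0.11 (SE 0.14), Gsdmd, the pore-forming effector, by 0.21 (SE 0.16) and Nlrp1b by -0.58 (SE 0.22). Their limma adjusted p ran from 0.121 for Casp1 and Nlrp1a to 1 for Aim2. Large single differences outside the named genes were Nrn1 (2.94, SE 0.31), Pdlim1 (1.92, SE 0.21), the DNA repair gene Smc6 (-1.99, SE 0.28), the antiviral kinase gene Eif2ak2 (-1.46, SE 0.20) and Rhob (-1.53, SE 0.31). Lin28a and Lin28b, which like Igf2bp3 encode fetal RNA-binding proteins, differed by 0.03 (SE 0.09) and -0.07 (SE 0.11).

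The 3 clusters with the smallest limma adjusted p of the whole table carry no gene name in the annotation used here and bear consecutive identifiers. TC0900002006.mm.1 fell by 9.85 on the log2 scale (SE 0.17, limma adjusted p 0.00173 over all clusters), from 14.52 and 14.24 in the arrays labelled WT to 4.57 and 4.49 in the arrays labelled KO. TC0900002005.mm.1 fell by 8.63 (SE 0.23, limma adjusted p 0.00858), and the third fell by 8.69 (SE 0.32, limma adjusted p 0.0283). In the arrays labelled KO the 3 clusters read 4.49 to 5.27, close to the array medians of 4.65 and 4.69, and the table has no background measure, so the size of each fall can be understated. Of the clusters without a listed gene 11.2% had an unadjusted p under 0.05 in that fit, against 7.58% of those with 1 gene.

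Single arrays stood apart within their group. Ly6c2 read 8.60 in WT replicate 1 and 13.33 to 14.07 in the other arrays, Apobec3 7.41 against 9.68 to 9.78, and Ifi206 11.56 against 7.25 to 7.61. In KO replicate 2, Trim12a read 6.40 against 9.75 in KO replicate 1, Trim5 8.05 against 10.64, and Cpne4 7.91 against 3.85.

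Bmi1 was higher in the arrays labelled KO. A shift shared by the genes around it was looked for in the 20 nearest protein-coding genes. Their median difference was 0.0425 (range -0.25 to 0.55, all below the 0.77 of Bmi1). This lay at the 88.3rd percentile of windows of 20 genes and below their upper limit of 0.075, so the median showed no such shift. The level of these genes was not taken into account. Genes that the cells hardly express could not show a shift, so the median does not exclude one. The adjacent Commd3, left out of these, had 0.48 (SE 0.13, limma adjusted p 0.383), and a shared shift stays open. Swapped labels stay open: Cdkn2a, which Bmi1 represses, was higher by 0.605 in the arrays labelled KO, the direction of a true deletion, but with a limma adjusted p of 0.377 and a level near the array medians. A cluster that reads exons outside the deleted part could give such a value whatever the deletion did, no table here holds single exons, and compensation by the cells of either genotype stays open and untested.

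Immunoglobulin transcripts were higher in the arrays labelled KO. RNA of antibody-secreting cells in the sorted cells may account for part of it: kappa variable segments, from another locus than the heavy chain, had a median of 0.16, above all 10000 matched random lists. The 9 plasma cell markers ran from Sdc1 (-0.03), Prdm1 (0.07), Tnfrsf17 (0.17), Ighg1 (0.21), Xbp1 (0.21) and Derl3 (0.27) to Mzb1 (0.40), Jchain (1.03, from 6.55 to 7.58) and Ighg2b (1.81). Of these, 2 are also in other lists. A sort on Foxp3 fluorescence after CD4 enrichment is meant to remove such cells, but how completely it did so was not examined. A heavy chain locus of another haplotype cannot be told apart from this, since the heavy chain segments had a median absolute difference of 0.475 against 0.105 in random lists but the kappa segments also moved (0.31 against 0.09). T cell receptor alpha variable segments had a median absolute difference of 0.30 against 0.15, 12 higher and 18 lower at an unadjusted limma p under 0.05, and a median of -0.04, whereas the 21 beta segments had 0.24 against 0.15, at the 95.7th percentile, and a median of 0.08, so random lists do not show how much receptor segments vary between samples, and an effect of genotype stays open.

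Large differences between the 2 arrays labelled WT lay near each other in the genome: the 100 protein-coding genes furthest apart held 28 pairs within 1 Mb with different symbol stems, against an upper limit of 14 under shuffled positions (permutation p = 1e-04, the smallest they can give). The difference between groups held 3 such pairs, against an upper limit of 15. Most of the 28 pairs lie in 1 region of chromosome 2 with zinc finger genes (Zfp442 7.60 and 9.97, Gm10130 8.94 and 12.13 in WT replicates 1 and 3). They combine the same few genes, so 1 region counts many times, and the permutation p does not show a tendency spread over the genome. With zinc finger and predicted genes left out, the 100 genes then furthest apart held 12 pairs, against 14. These gene classes were chosen after the chromosome 2 region was seen. Leaving them out removes its pairs whatever their cause, so families of similar neighbouring genes stay open. Khdc1a and Tram2 on chromosome 1 form a second group. Genetic background that differs between animals cannot be told apart from such families. The 2 arrays labelled KO held 11 pairs, against 14, and strain markers were not analysed here.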
